A study of Medicago truncatula with 21 samples.

How the data were processed

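RNA was measured by sequencing in 21 seed libraries of the model legume Medicago truncatula, 3 for each of 7 groups. Per the labels' protocols, seeds were taken out of the pods and frozen, RNA was extracted with a column kit, mRNA was enriched and converted to cDNA with random primers, and short single reads were produced on a BGISEQ-500 instrument. Salmon is named in the submitters' processing notes without a version. The genome build, the annotation and the normalization tool are not given in the sources used here.

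The values deposited by the authors carry the name FPKM, but they are a signal on the scale of normalized read counts. Library totals lay between 18365151 and 24032451, and the value of 1 read, estimated from the smallest values in each library, lay between 0.80 and 1.20. Within each stage the median ratio of a library to the geometric mean of its stage was the same in every library, at 1.00 at 13 days after pollination (DAP) and 1.01 at 24 DAP and in mature seeds. Over all 21 libraries that ratio was 1.55 to 1.58 at 13 DAP, 0.552 to 0.560 at 24 DAP and 1.11 to 1.13 in mature seeds, so the deposited values had been scaled separately for the 3 stages. Among low values, 61.6 to 78.9% at 13 DAP, 45.8 to 74.5% at 24 DAP and 90.2 to 95.9% in mature seeds lay within 0.1 of a whole multiple of the value of 1 read, so whole reads were not recovered and no count model was used. Dividing each total by the value of 1 read gave an estimated depth of 18409927 to 23371739 reads per library.

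Groups and replicate numbers came from the sample labels. The design text of the series says that replicates were seeds from different plants, but it names mutant lines of another gene than the title and the sample labels do; the sample labels were followed. If the replicates were not separate plants, p-values measure only the spread between these samples. Replicate pairs within a group had log2 correlations of 0.962 to 0.990, and their counts differed by more than sampling noise in every pair, with a chi-square per gene of at least 2.55.

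The plan, fixed before the data were examined, was a limma fit of log2(FPKM + 1) over all 21 libraries with a filter of 1 in at least 3 libraries. Because the unit and the separate scaling differed from that plan, the main test was limma (version 3.58.1, in R 4.3.3, with an intensity trend) on log2(normalized count + 1), fitted within a stage on 6 libraries at 13 or 24 DAP and on 9 libraries in mature seeds. Genes with at least 10 normalized counts in at least 3 libraries of the fit were kept. The pseudocount of 1 makes fold changes of low genes smaller than they are. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. Whether the genotype effect differed between stages was tested as the difference of the within-stage differences over 12 libraries. A scale factor common to a stage drops out of it, except in part for low genes, because of the pseudocount and the filter. R108 stages were described on a median-of-ratios scale common to all 21 libraries, with no test, since stage and scaling set coincide.

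The 44473 identifiers include 85 of the plastid genome and 72 of the mitochondrial genome. The files do not pair identifiers with gene names, and 0 of them matched the reference gene table of assembly MtrunA17r5.0-ANR. The 20 gene lists fixed beforehand, the named-gene rule, which needed descriptions, and the check of the ABI4 transcript against the labels were therefore not run. At most 2 identifiers that rose and 2 that fell are named, chosen after the data were seen as those called in the same direction in all 4 comparisons of a mutant with R108, ranked by their smallest change. Gene sets chosen after the data were seen were the plastid and mitochondrial transcripts and genes at least 4-fold higher in R108 at either of the other stages than the one compared, so that set and comparison share no library. These levels were set across separately scaled stages. Sets were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all from limma. Camera compares a set with the other genes, whereas fry tests it against no change, so the p-values of the methods answer different questions.

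The replicate numbers in the labels recur in every group, and the labels do not say what a number shares. Deviations of same-numbered abi4-1 and R108 libraries from their group means correlated at 0.154 to 0.293 at 13 DAP and at 0.102 to 0.339 at 24 DAP, above 0.1 for each pair, so the numbers were taken to pair libraries at these stages. In mature seeds the correlations were between -0.0392 and 0.0683, and the numbers were not taken as pairs. The main fits at 13 and 24 DAP did not use the pairs, and a fit with the replicate number as a block is given as an alternative.

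The fits were tested on simulated counts drawn for the real genes with 100 genes changed 2-fold and 100 changed 4-fold. At 13 DAP, with 22499 genes, 70 of the 2-fold and 98 of the 4-fold changes were recovered. At 24 DAP, with 19508 genes, 79 and 96 were recovered, in mature abi4-1, with 19429 genes, 97 and 100, and in mature abi4-2 93 and 100. False calls made up 2.89, 6.91, 2.96 and 6.31% of the calls in these simulations. The changed genes were drawn only from genes with means well above the filter on low values. The recovered counts therefore do not apply to genes near that filter. Of 200 random sets of 79 simulated genes, which could include changed ones, camera gave p under 0.05 for 1.5, 1.5, 1 and 1.5%. The simulated genes were drawn independently. In mature abi4-1 seeds the estimated correlation was 0.340 among plastid and 0.357 among mitochondrial transcripts, so these shares were not shown to hold for the organelle sets.

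Alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, only the groups compared, limma arrayWeights, a replicate block, a minimum fold of 2 and leaving out each library in turn. The plan itself, a fit over all 21 libraries with a filter of 1, was run as an alternative after the data were seen, as were each of its parts alone. Also added then were scaling to the column total or the upper quartile, other definitions of the stage sets, and a paired exact sign-flip permutation test by replicate number of the share of the 5 leading transcripts.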

Results

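Transcript levels were measured in seeds of Medicago truncatula, a small legume related to alfalfa, from the wild-type line R108 and from lines with a Tnt1 retrotransposon insertion in ABI4. ABI4 is known as a transcription factor of the AP2/ERF family that acts in abscisic acid and sugar signalling. R108 and the abi4-1 line were sampled at 13 DAP, at 24 DAP and as mature seeds, and the abi4-2 line as mature seeds, with 3 libraries in each of the 7 groups. Library totals were 21035365 to 24032451 normalized counts at 13 DAP, 18365151 to 22139476 at 24 DAP and 19162030 to 20345780 in mature seeds. Between 18147 and 22519 genes reached 10 normalized counts in a library.

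The files do not pair identifiers with gene names, so the ABI4 transcript itself was not examined against the labels. MtrunA17_Chr5g0437371 or another lowered identifier below may be ABI4 itself, and its low level would then be a check of the labels rather than a change downstream of ABI4. In all 4 comparisons of a mutant with R108, 40 genes were called higher and 17 lower, out of 16157 tested in all 4. Another 18 were called in all 4 but in differing directions. Lists drawn independently would share 0.680 higher and 0.396 lower genes, although both mature comparisons use the same R108 libraries. MtrunA17_Chr5g0437371, among the 17, stood at 251 ± 28.0 normalized counts in R108 and 3.99 ± 2.26 in abi4-1 at 13 DAP, and at 164 ± 19.2 and 1.58 ± 1.59 at 24 DAP (SD, n = 3). In mature seeds it stood at 525 ± 54.8 in R108, 12.3 ± 5.68 in abi4-1 and 24.3 ± 3.04 in abi4-2. MtrunA17_Chr6g0454201 stood at 372 ± 95.9 in R108 and 7.05 ± 2.84 in abi4-1 at 13 DAP, and at 262 ± 21.4 and 3.66 ± 1.90 at 24 DAP. MtrunA17_Chr3g0140051 was higher in the mutants, at 96.1 ± 19.1 in abi4-1 against 3.36 ± 3.26 in R108 at 13 DAP and at 3590.4 ± 356 against 6.73 ± 6.08 at 24 DAP. In mature R108 it was listed at 0 in each library, against 24.3 ± 5.69 in abi4-1 and 41.9 ± 21.2 in abi4-2. MtrunA17_Chr2g0300561 stood at 464 ± 124 in abi4-1 and 94.9 ± 48.0 in R108 at 13 DAP, a log2 change of 2.39 ± 0.39 (SE, limma adjusted p = 0.0192) that lost its call without R108 replicate 3, abi4-1 replicate 2 or abi4-1 replicate 3, with adjusted p from 0.0727 to 0.117. For MtrunA17_Chr3g0140051 at 13 DAP the call was lost with a pseudocount of 0.1, at an adjusted p of 0.0635.

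At 13 DAP, the earliest stage sampled, abi4-1 was compared with R108. Of 22499 genes tested, 283 were higher and 271 lower in abi4-1, and 73 rose and 104 fell by at least 4-fold. Present in each R108 library at 10 or more normalized counts and below 3 in each abi4-1 library were 22 genes, and 6 showed the opposite. Of 71 plastid transcripts 0 were called, with a median log2 change of -0.082 (camera adjusted p = 0.388), and of 26 mitochondrial transcripts 0 were called, with a median of -0.17 (adjusted p = 0.388). With column totals the plastid median was 0.012, and both sets passed (camera adjusted p = 0.0282 and 0.0283), and without single libraries the plastid median ran from -0.38 to 0.28. The mitochondrial median then ran from -0.66 without R108 replicate 1 (camera adjusted p = 0.000103) to 0.076 without abi4-1 replicate 1 (adjusted p = 0.740), and it also passed without abi4-1 replicate 2, at -0.36 (adjusted p = 0.0151). Among 5957 genes higher in R108 at 24 DAP than in mature seeds, 132 were higher and 154 lower in abi4-1, and among 2098 genes with the opposite profile 31 were higher and 10 lower; neither set passed camera (adjusted p = 0.433 for each). The 5 transcripts that lead the 24 DAP libraries made up 4.22 ± 2.80% of the total in R108 and 1.77 ± 0.297% in abi4-1 (two-sided exact permutation p = 0.3, smallest possible 0.1). The share was higher in R108 in all 3 same-numbered pairs, at 7.04 against 2.02%, 1.45 against 1.44% and 4.16 against 1.84% (two-sided exact sign-flip permutation p = 0.25, the smallest that 3 pairs allow). With the replicate number as a block 834 genes were called in place of 554, and leaving out a library gave from 164 calls, without R108 replicate 3, to 921, without R108 replicate 2. The share of calls that were higher was 51.1%, and 62.4% with libraries scaled to their column total (414 higher and 249 lower). Without abi4-1 replicate 1, 2 or 3 falls outnumbered rises, and the share that were higher was 39.3, 40.9 and 29.8%.

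At 24 DAP, in the same comparison, 1881 genes were higher and 1249 lower in abi4-1 among 19508 tested, and large changes were mostly rises, with 333 genes up and 88 down by at least 4-fold. Near-absent in R108 and present in abi4-1 were 68 genes, and 20 were the reverse, by the bounds of 3 and 10 normalized counts. Genes higher in R108 at 13 DAP than in mature seeds rose on balance, with 909 of 5678 higher, 363 lower and a median log2 change of 0.063 (camera adjusted p = 0.0225); this call was not kept with an estimated correlation (adjusted p = 0.687) or in the planned fit over all 21 libraries with a filter of 1 (median 0.012, adjusted p = 0.446). Of 2735 genes with the opposite profile, 186 were higher and 292 lower (median log2 change -0.057, camera adjusted p = 0.0533). The set passed with the replicate number as a block (adjusted p = 0.0466) but not with an estimated correlation (adjusted p = 0.687). Fry, which tests the set against no change, did not pass either (adjusted p = 0.593). Camera also passed with both other definitions of the stage sets (adjusted p = 0.0357 and 0.0497). Omissions gave medians from -0.094, without abi4-1 replicate 3 (camera adjusted p = 0.00231), to -0.018, without abi4-1 replicate 2 (adjusted p = 0.875). The set passed as well without R108 replicate 2 or abi4-1 replicate 1, but not without R108 replicate 1 or 3. Of 67 plastid transcripts 2 were higher and 7 lower, with a median of -0.29 (camera adjusted p = 0.0274), also not kept with an estimated correlation (adjusted p = 0.687) or in the planned fit (median -0.26, adjusted p = 0.167). Of 7 mitochondrial transcripts 0 were called, with a median of -0.083 (camera adjusted p = 0.427). Their median ran from -0.42 without abi4-1 replicate 3 (camera adjusted p = 0.0640) to 0.23 without abi4-1 replicate 2 (adjusted p = 0.935). A handful of transcripts dominated these seeds: the 5 most abundant made up 52.8 ± 1.44% of the total in R108 and 53.1 ± 1.52% in abi4-1, a difference within the spread between replicates (two-sided exact permutation p = 0.8). Without abi4-1 replicate 1, 2 or 3 the calls numbered 1944, 1925 and 1876. Rises made up 60.1% of the calls, and 73.1% with column totals (1839 higher and 677 lower). With the replicate number as a block 4098 genes were called, and rises made up 56.2% (2305 higher and 1793 lower). The share of rises was 54.7% in the planned fit (2332 higher and 1932 lower). It was 52.6% with all 21 libraries in 1 fit (1980 higher and 1787 lower).

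Whether the effect of abi4-1 differed between 13 and 24 DAP was tested as an interaction. Relative to 13 DAP, the change at 24 DAP was more positive for 898 genes and more negative for 550, among 23225 tested with limma. With the replicate number as a block these counts were 1202 and 886. Of the genes higher in abi4-1 at 13 DAP and tested at both stages, 116 of 247 were also higher at 24 DAP, against 22.7 for independent lists (one-sided Fisher's exact p = 1.1e-54), and of the lower ones 88 of 210, against 13.1 (p = 2.0e-50); 34 genes were called in opposite directions. Between 13 DAP and mature abi4-1 seeds, 104 of 179 genes higher at 13 DAP were also higher, against 42.4 (one-sided Fisher's exact p = 4.2e-23), but lower genes shared 36 of 128, against 29.9 (p = 0.122), and 52 were called in opposite directions. Plastid and mitochondrial transcripts had 0 calls each in this interaction, among 74 and 26 tested, with median log2 differences of -0.16 and 0.33 (camera adjusted p = 0.269 for each). These depended on single libraries at 13 DAP: the plastid median was -0.52 without abi4-1 replicate 1 (adjusted p = 9.4e-05), -0.36 without R108 replicate 3 (adjusted p = 0.0138) and 0.11 without abi4-1 replicate 2 (adjusted p = 0.486), and the mitochondrial median was 0.80 without R108 replicate 1 (adjusted p = 0.00509). Without R108 13 DAP replicate 3 the interaction gave 851 calls in place of 1448. The Fisher's exact tests above treat genes as independent draws, which they are not, so their p-values do not measure the spread between libraries.

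In R108 itself, the 5 transcripts that made up 52.8% of the library total at 24 DAP were at 0.239 ± 0.00296% in mature seeds. On the common median-of-ratios scale, 1544 genes were at least 4-fold higher at 24 than at 13 DAP and 2376 at least 4-fold lower, with groups that did not overlap (chance gives 10% for 3 against 3). From 24 DAP to mature seeds, 3280 were higher and 6294 lower. No test was made, since the stages had been scaled separately, and the balance depended on the scale: as deposited the splits were 649 against 7746 and 6415 against 4134, and with column totals 696 against 6535 and 6534 against 4116.

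In mature abi4-1 seeds, compared with R108 in a fit of 9 libraries, organelle transcripts changed in opposite directions. Plastid-encoded transcripts fell, with 76 of 79 lower, 1 higher and a median log2 change of -2.03 (camera adjusted p = 1.9e-43; with an estimated correlation, adjusted p = 0.0381). Their share of the library was 0.496 ± 0.0633% in R108 and 0.110 ± 0.00894% in abi4-1 (SD, n = 3), and each R108 library lay above each abi4-1 library (two-sided exact permutation p = 0.1, the smallest possible). Mitochondrial-encoded transcripts rose, with 29 of 43 higher, 0 lower and a median of 0.91 (camera adjusted p = 2.3e-07; not kept with an estimated correlation, adjusted p = 0.170). Genes higher in R108 at 13 than at 24 DAP rose, with 251 of 641 higher and 63 lower, a median of 0.36 (camera adjusted p = 1.4e-05; with an estimated correlation, adjusted p = 0.0381). That call depended on the scale used to define the set: with sets from values as deposited the median was 0.063 and the call ended (camera adjusted p = 0.107), and with a 2-fold bound the median was 0.19 (adjusted p = 0.00121). It also ended in the planned fit, whose filter keeps more low genes, with a median of 0 (adjusted p = 0.0508). Genes with the opposite profile also rose, with 542 of 1115 higher, 174 lower and a median of 0.35 (camera adjusted p = 7.3e-08; with an estimated correlation, adjusted p = 0.146). Over all 19429 genes tested, 4662 were higher and 4304 lower, and by at least 4-fold 574 rose and 147 fell. Of these falls 14 lay within a run of 20 consecutive tested identifiers on chromosome 4, whose sum followed that of the plastid transcripts over the 6 libraries at 13 DAP. The 5 transcripts that lead at 24 DAP made up 0.518 ± 0.0428% of mature abi4-1 libraries, above the 0.239% of R108 in each library (two-sided exact permutation p = 0.1). Scaling to the upper quartile moved the median of all genes from -0.0026 to 0.11 and the calls to 6224 higher and 2823 lower, so the balance of rises and falls among small changes depends on the scale.

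**Figure D1:**
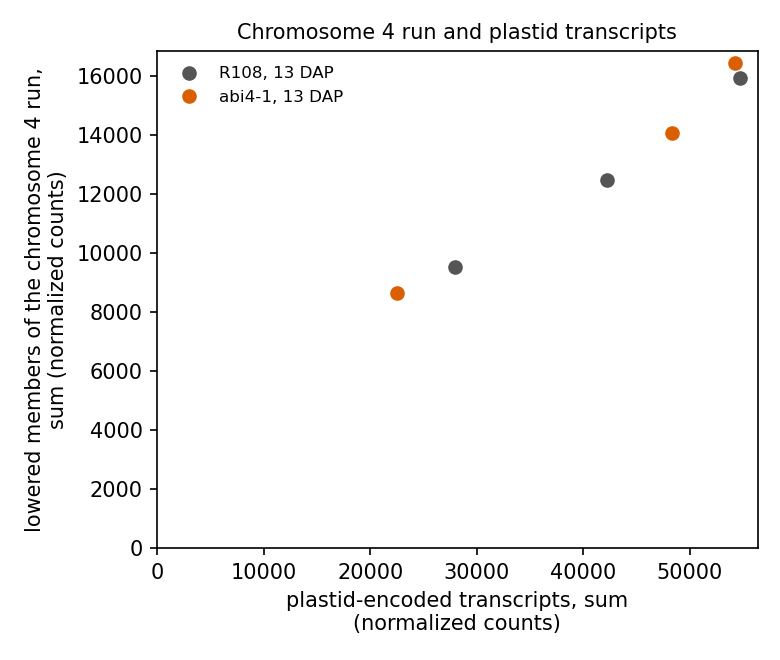
Sum of the 14 lowered members of the run on chromosome 4 (y axis, normalized counts) against the sum of plastid-encoded transcripts (x axis, normalized counts) in the 6 libraries at 13 DAP (points, coloured by line). The sums of the members run from 8652 to 16429.7 and rise with the plastid sums.

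**Figure D2:**
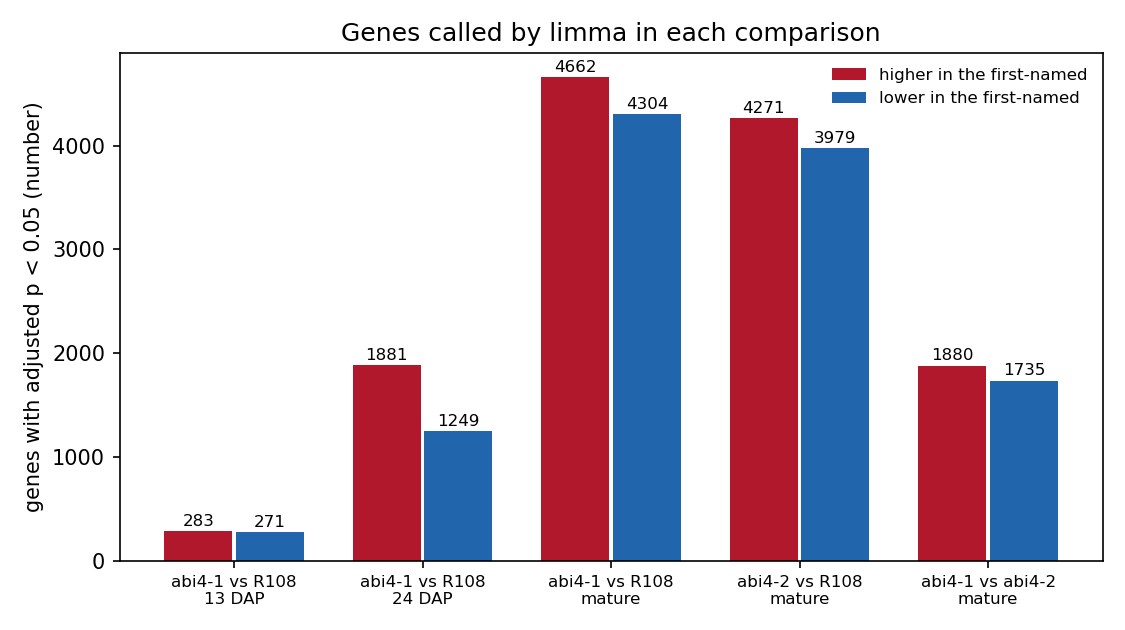
Number of genes with an adjusted p under 0.05 in limma (y axis) for each comparison within a stage (x axis), as bars from 0 for genes higher and lower in the first-named line. Calls rise from 283 and 271 at 13 DAP to 4662 and 4304 in mature abi4-1 seeds.

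Mature seeds of the second allele, abi4-2, had organelle transcripts that changed in the same directions against R108. Plastid transcripts fell, with 75 of 79 lower, 3 higher and a median log2 change of -1.90 (camera adjusted p = 7.5e-46; with an estimated correlation, adjusted p = 0.0425), at 0.114 ± 0.00152% of the library. Mitochondrial transcripts rose, with 41 of 43 higher, 0 lower and a median of 2.06 (camera adjusted p = 4.4e-19; with an estimated correlation, adjusted p = 0.0483), from 0.0119 ± 0.000233% of the library in R108 to 0.0574 ± 0.0161% in abi4-2, with 0.0275 ± 0.00622% in abi4-1. Genes higher in R108 at 13 than at 24 DAP rose, with 231 of 641 higher and 70 lower (median 0.34, camera adjusted p = 4.7e-05; with an estimated correlation, adjusted p = 0.0467), and with sets from values as deposited the median was 0.12 (adjusted p = 0.00438), while in the planned fit the median was 0 and the call ended (adjusted p = 0.0748). Of the genes with the opposite profile 421 of 1115 were higher and 193 lower (median 0.18, camera adjusted p = 0.000838; with an estimated correlation, adjusted p = 0.299), and the call ended with sets at 2-fold (median 0.068, adjusted p = 0.119) and in the planned fit (median 0.13, adjusted p = 0.0748). In all, 4271 genes were higher and 3979 lower, and by at least 4-fold 601 rose and 168 fell. The 5 transcripts that lead at 24 DAP made up 0.721 ± 0.0810% of these libraries. With upper-quartile scaling the median of all genes moved to 0.14 and the calls to 6260 higher and 2225 lower.

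**Figure D3:**
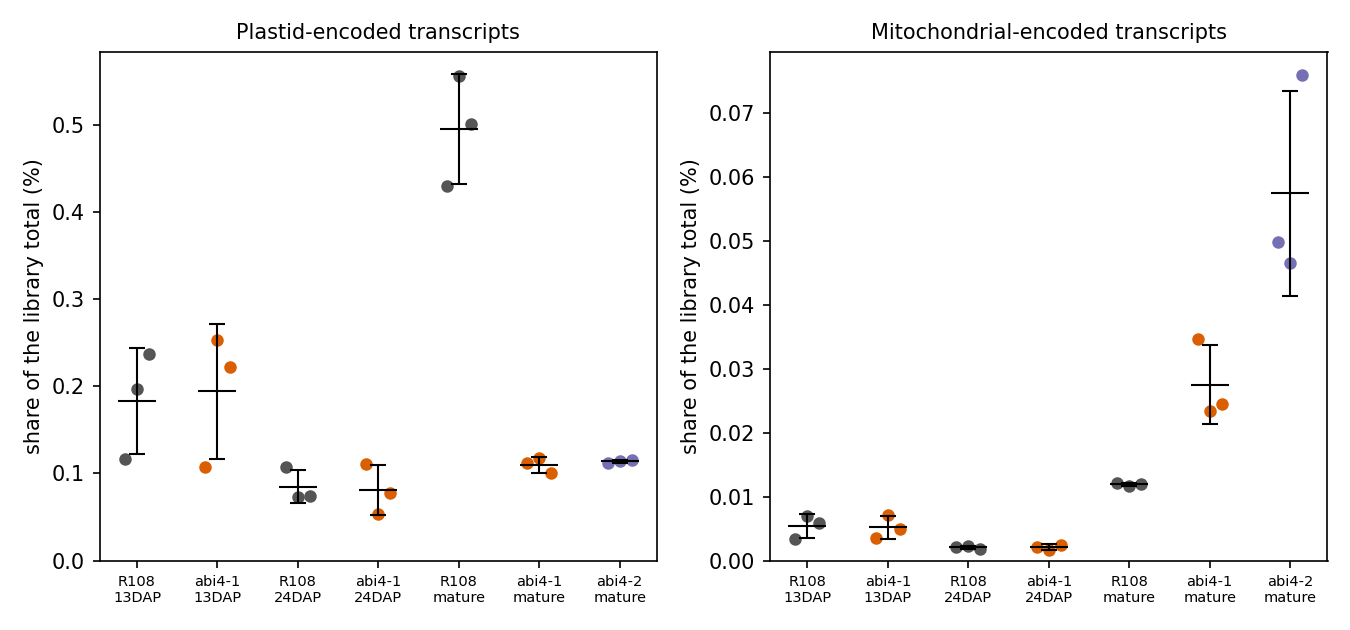
Share of the library total (y axes, %) taken by plastid-encoded and mitochondrial-encoded transcripts in each library (points) of each group (x axes), with the group mean and SD as black bars. Mature R108 libraries have a mean plastid share of 0.496%, against 0.110% in abi4-1 and 0.114% in abi4-2.

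Both alleles were compared with the same 3 R108 libraries. Called higher in both were 3186 genes, against 1025 for independent lists, and lower in both 2775, against 881; 73 were called in opposite directions. The log2 changes of the alleles correlated at 0.854 across genes, with a covariance of 0.60. In 50 simulations of unchanged groups against shared controls the correlation was 0.502, the covariance 0.030 and the number of genes called in both 0.1 on average. The observed covariance was 0.57 above the simulated one. These simulations changed no gene, so few calls in both were bound to follow. That number therefore does not measure what shared controls add when genes do change. Noise was drawn separately for each gene, so a shift of the R108 libraries common to many genes was not simulated. Below 3 normalized counts in each mature R108 library and at 10 or more in each of the abi4 libraries were 55 genes, of which 31 reached a mean of 10 in R108 at 13 or 24 DAP, on separately scaled values; 5 genes showed the reverse. The 3 controls cannot be split into parts of 2, so part of the excess of shared calls may come from them.

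**Figure D4:**
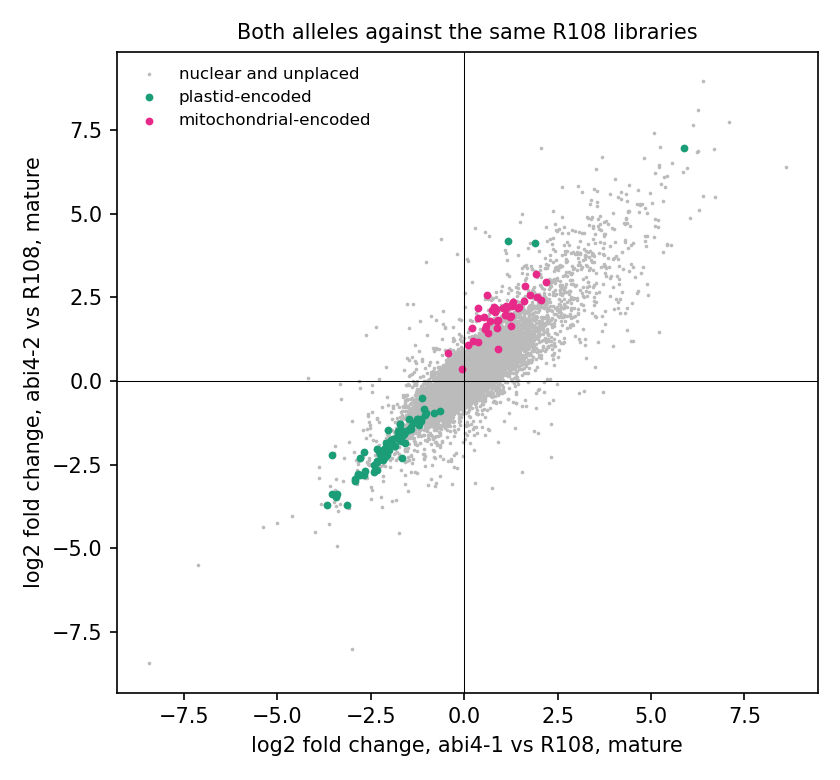
Log2 fold change against mature R108 of each gene tested in abi4-1 (x axis) and abi4-2 (y axis), with plastid-encoded and mitochondrial-encoded transcripts in colour. Plastid transcripts have medians of -2.03 and -1.90 and mitochondrial transcripts of 0.91 and 2.06.

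Between the alleles, mitochondrial transcripts differed and plastid transcripts were not shown to differ. Mitochondrial transcripts were lower in abi4-1 than in abi4-2, with 29 of 43 called lower, 0 higher and a median log2 difference of -0.98 (camera adjusted p = 2.8e-16; not kept with an estimated correlation, adjusted p = 0.189). Of 79 plastid transcripts 2 were higher and 5 lower (median -0.050, camera adjusted p = 0.201). Omissions gave plastid medians from -0.10 without abi4-2 replicate 1 to 1.2e-05 without abi4-1 replicate 3. The plastid set passed only without abi4-1 replicate 2 (median -0.066, camera adjusted p = 0.0450). Genes higher in R108 at 24 than at 13 DAP were higher in abi4-1, with 289 of 1115 higher, 96 lower and a median of 0.15 (camera adjusted p = 3.0e-06; not kept with an estimated correlation, adjusted p = 0.305), and of those with the opposite profile 78 of 641 were higher and 36 lower (camera adjusted p = 0.287). In all, 1880 genes were higher and 1735 lower in abi4-1, of which 430 differed by at least 2-fold. With upper-quartile scaling the balance turned, to 1641 higher and 1932 lower. A fit over all 21 libraries with the same genes called 1850 in place of 3615, and the planned fit, with its filter of 1, called 936 higher and 984 lower.

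The effect of abi4-1 also differed between mature seeds and 24 DAP. Plastid transcripts moved down relative to 24 DAP, with 60 of 81 called lower, 1 higher and a median log2 difference of -1.64 (camera adjusted p = 6.2e-26; not kept with an estimated correlation, adjusted p = 0.0599). Mitochondrial transcripts moved up, with 6 of 39 called higher, 0 lower and a median of 0.88 (camera adjusted p = 0.00117; not kept with an estimated correlation, adjusted p = 0.133). Only 7 mitochondrial transcripts passed the filter at 24 DAP itself, so most of the 39 were tested because of their level in mature seeds. Their change at 24 DAP was hardly measurable, and the pseudocount makes it smaller. Over 22163 genes tested with limma, 2689 moved up and 2121 down. Of the genes higher in abi4-1 at 24 DAP and tested at both stages, 646 of 1340 were also higher in mature seeds, against 327 for independent lists (one-sided Fisher's exact p = 1.6e-87), and of the lower ones 412 of 1031, against 247 (p = 2.9e-32), while 378 genes were called in opposite directions. With upper-quartile scaling the interaction had 3298 genes up and 1648 down. As above, the p-values of Fisher's exact test treat genes as independent draws and do not measure the spread between libraries.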

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

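Among the tests below, those of carry-over and of scaling were chosen after the results they bear on had been seen, at least in part, and the set comparisons were chosen after the data were seen.

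A difference between groups singled out 7 results, each from a test of the difference itself. The abi4-1 and abi4-2 alleles differed in 3615 genes in mature seeds, and the real grouping was the only 1 of the 10 splits of the 6 libraries to reach that count, with at most 1 gene in the others. The effect of abi4-1 differed between 13 and 24 DAP in 1448 genes. Of the 100 splits of the 12 libraries 3 gave as many, the real grouping included, and the highest other gave 1520. The other 2 kept the true genotypes at 24 DAP and mixed them at 13 DAP, and splits of that kind gave 557 to 1520 genes. A count of this size can therefore come from an effect at 24 DAP alone. The 1448 and the splits come from fits without the replicate number, and with it as a block the interaction called 2088 genes. Between 24 DAP and mature seeds the effect differed in 4810 genes, reached by 1 of 100 splits, the real grouping. Splits that kept the true genotypes only in mature seeds gave 1902 to 2601 genes, and those true only at 24 DAP gave 246 to 351. Splits that exchange the lines at 1 stage were not among the 100, so this count does not exclude chance. The other flagged values were sets: mitochondrial transcripts between the alleles (median log2 difference -0.98), genes higher in R108 at 24 than at 13 DAP between the alleles (0.15), plastid transcripts between mature seeds and 24 DAP (-1.64) and mitochondrial transcripts between mature seeds and 24 DAP (0.88). Most mitochondrial transcripts in the last set did not pass the filter at 24 DAP itself. With camera at an estimated correlation none of the 4 sets kept its call (adjusted p = 0.189, 0.305, 0.0599 and 0.133, in that order). Fry, which tests a set against no change rather than against other genes, gave adjusted p = 0.00856, 0.0356, 0.000755 and 0.00371.

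For the comparisons within a stage, 10 splits are too few for a share under 0.05. The real grouping gave 554 calls at 13 DAP and 3130 at 24 DAP, with at most 0 in the other splits, including those that part all 3 numbered pairs. In mature seeds it gave 8966 calls for abi4-1 and 8250 for abi4-2, with at most 1 in the others. In each of these comparisons 1 split, the real one, reached the count.

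Plastid transcripts were lower and mitochondrial transcripts higher in mature seeds of both alleles, although with camera at an estimated correlation the mitochondrial call of abi4-1 was not kept (adjusted p = 0.170) and that of abi4-2 was (adjusted p = 0.0483). Carry-over of RNA without poly(A) tails, differing between libraries, would by itself move both organelles the same way. The smaller mitochondrial median, that of abi4-1, was 0.91, at least 0.79 without any 1 library, while the plastid medians were -2.03 and -1.90. These opposite signs were part of the pattern when the test was chosen, so they are no separate test. Carry-over behind 1 of the changes, with another cause for the other, remains open. Over 4 scalings and both alleles the plastid median closest to 0 was -1.77. The scalings moved the median of all genes to at most 0.14, too little to bring the plastid median near 0. The fall thus exceeds any difference between these scalings. Median of ratios and the values as deposited are nearly the same within a stage. A difference in the plants or harvest of the mature R108 seeds, shared by both comparisons, remains open, as does an effect of ABI4 itself; neither was tested. That the organelles of mature abi4 seeds differ biologically from those of R108 is therefore only a hypothesis.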

How the results depend on the processing

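Some alternatives were added after the data were seen: the plan itself (all 21 libraries, filter of 1), each of its parts alone, the column-total and upper-quartile scalings, the stage scales and the stage-set definitions. Over results that answer a comparison, 346 alternative values stayed on their side of the threshold or within 1.5 times, 25 moved and 24 were weaker; the cause was not tested unless stated. No set or identifier called in the main comparison changed to the opposite sign, but the balance of rises and falls did: at 13 DAP from 283 against 271 to 54 against 127 without abi4-1 replicate 3, and between the alleles from 1880 against 1735 to 1641 against 1932 with upper-quartile scaling. Within a stage, median-of-ratios scaling changed almost nothing, since the values had been scaled that way. With limma arrayWeights, calls at 13 DAP rose from 554 to 1785 and the interaction of 24 with 13 DAP from 1448 to 2553. Requiring a fold of at least 2 left 368 genes at 13 DAP, 1231 at 24 DAP, 2225 and 2074 in mature abi4-1 and abi4-2, 430 between the alleles, 1455 shared by the alleles and 2382 for the interaction of mature seeds with 24 DAP, by construction. Between the alleles the fit over all 21 libraries gave 1850 genes and the planned fit 1920; the latter gave 1069 at 13 DAP and ended 5 set calls: at 24 DAP plastid (-0.26, adjusted p = 0.167) and high at 13 DAP (0.012, 0.446), in mature seeds high at 13 DAP in abi4-1 and abi4-2 (median 0 for each, 0.0508 and 0.0748) and high at 24 DAP in abi4-2 (0.13, 0.0748).

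With the replicate block 834 genes were called at 13 DAP; it moved no other count by over 1.5 times and changed no other set call except the set of genes high in mature R108 at 24 DAP (adjusted p = 0.0466).

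Leaving out 1 library gave 164 to 921 calls at 13 DAP, where each of the 6 omissions moved the count by over 1.5 times: 297, 921 and 164 without R108 replicates 1, 2 and 3, and 257, 279 and 181 without abi4-1 replicates 1, 2 and 3. At 24 DAP it gave 1876 to 2820, and for the interaction of 24 with 13 DAP 851 to 1801. Without R108 13 DAP replicate 2 both rose, to 921 and 1801. In mature seeds the ranges were 7540 to 8215 for abi4-1 and 6764 to 7838 for abi4-2.

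With an estimated correlation the 24 DAP sets lost their calls, and fry, a test against no change, did not pass: plastid (median -0.29, adjusted p = 0.687 and 0.593) and high at 13 DAP (0.063, 0.687 and 0.245). The fit over all 21 libraries also ended them (adjusted p = 0.0816 and 0.0588). Omissions gave plastid medians from -0.48 to -0.054, ending the call without R108 replicate 1 or abi4-1 replicate 2, and 0.027 to 0.088 for the other set, ending it without R108 replicate 3 or abi4-1 replicate 2. With an estimated correlation, further calls ended at unchanged medians: mitochondrial in abi4-1 (0.91), between the alleles (-0.98) and against 24 DAP (0.88), plastid against 24 DAP (-1.64), and genes high at 24 DAP in abi4-1 (0.35), in abi4-2 (0.18) and between the alleles (0.15). With stage sets from deposited values, genes high at 13 DAP had a median of 0.063 in mature abi4-1 (adjusted p = 0.107); with sets at 2-fold, genes high at 24 DAP had 0.068 in mature abi4-2 (adjusted p = 0.119). The R108 change from 13 to 24 DAP covered 3920 genes on the common scale, 8395 as deposited and 7231 with column totals. Of 242 alternatives for the named identifiers 4 ended a call and 0 reversed; in 22 more, 21 of them omissions, the identifier failed the filter and was not tested. Among sets not called, 17 values gained a call, 2 of them across 0, and 18 others moved across 0 uncalled, many for organelle sets without a 13 DAP library: the plastid median was called at -0.38 without R108 replicate 1, -0.29 without abi4-1 replicate 2 and 0.28 without abi4-1 replicate 1. Count models were not run, for want of counts.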

Other observations

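All tests in this part, those of neighbours, of the run on chromosome 4, of seed age and of depth, were chosen after the values they use had been seen, at least in part. Genes called in mature abi4 seeds by at least 4-fold lay next to each other more often than shuffled positions would give. Within 3 places of each other on a chromosome and in the same direction were 167 pairs in abi4-1, against 52.2 on average and at most 75 in 1000 shuffles, and 186 in abi4-2, against 53.9 and at most 78. At 13 DAP there were 28 such pairs, against 2.18 on average, and at 24 DAP 70, against 18.1. Each of these reached the smallest p that 1000 shuffles can give, 0.000999. Tandem copies of related genes, which can share reads, were not identified here.

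A run of 20 consecutive tested identifiers on chromosome 4 held 14 that were lower by at least 4-fold in mature abi4-1 seeds, against at most 4 for such a run in 200 shuffles, and 11 of the 14 were also lower by as much in abi4-2. Their sum was 7883 normalized counts in R108, 1431 in abi4-1 and 1383 in abi4-2. Loss of the region was examined in abi4-1 at 13 DAP, where the 6 members tested had a median log2 change of -0.10 and 0 were called lower. This cannot decide whether the region is present if its reads come from the plastid genome, a possibility given below. The other lowered members were not tested at 13 DAP, and abi4-2 was not sampled then. Over the 6 libraries at 13 DAP the sum of the 14 lowered identifiers followed the sum of the plastid transcripts, with r = 0.990 (exact permutation p = 0.00278) and rho = 0.943 (exact permutation p = 0.0167). It was the only relation of this kind computed, and r was 0.989 without the 2 farthest libraries and 0.993 after centring each genotype. The permutations treat the 6 libraries as exchangeable, although replicate numbers were taken to pair them. Replicate 1 had the lowest of both sums in each line. Reads shared between the plastid genome and copies of plastid sequence in this region are a candidate explanation, and part of the nuclear falls in mature seeds could then be plastid transcripts counted elsewhere.

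The R108 libraries at 13 DAP differed among themselves more than those of abi4-1 in the share of the 5 transcripts that lead at 24 DAP, with 1.45 to 7.04% of the total against 1.44 to 2.02%. They did not in the plastid share (SD 0.0614% against 0.0773%), and log2 correlations between replicates were alike (0.973 to 0.986 against 0.976 to 0.983). Chi-square per gene between replicates was larger for each R108 pair, at 26.4 to 93.96 against 9.8 to 20.58 in abi4-1. The share of the 5 most abundant transcripts of each library also ranged more widely in R108, at 2.7 to 8.48% against 3.24 to 3.61%. Across 25167 genes, which are not independent replicates, the difference between R108 replicates 1 and 2 correlated at r = 0.308 with the change from 13 to 24 DAP in abi4-1, which shares no library with it, and that between R108 replicates 3 and 2 at 0.247. These 2 values share replicate 2, and between R108 replicates 1 and 3 r was 0.120. For the abi4-1 pairs 1 and 2, and 3 and 2, r with the change in R108 was 0.187 and 0.0907. For the abi4-1 pair 1 and 3 it was 0.119, close to that of the same R108 pair. Over all pairs of replicates the absolute r was 0.0744 to 0.357 at 24 DAP and at most 0.0393 in mature seeds. A difference in seed age at harvest may underlie part of the spread. Library depth is argued against, since the depths of replicates 1 and 3 were 0.857 and 0.999 of that of replicate 2.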
